A study of Rattus norvegicus with 23 samples.

How the data were processed

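Gene expression was measured in CA3 tissue from 23 male Long-Evans rats, 1 array per animal. Per the labels' protocols, the animals were killed after behavioural testing, the hippocampal fields were separated by microdissection, total RNA was extracted with Trizol and purified on RNeasy columns, and biotin-labelled cRNA was hybridised to Affymetrix Rat Genome 230 2.0 arrays by a core facility. The labels number the animals of each group as biological replicates, with aged impaired replicates 1 to 8, aged unimpaired replicates 1, 2, 4, 6, 7 and 8, and young replicates 1 to 9. Impairment was assigned from a learning index in the water maze, per the labels' protocols. The index of each animal was not used here, and neither were any other aged unimpaired animals, other hippocampal fields or the scanner images.

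The deposited values are on the log2 scale, from GCRMA, per the submitters' processing notes. GCRMA corrects for background with the probes' sequence, normalizes arrays to a common distribution and summarises the probes of a probe set, so that differences shared by most probe sets of an array are removed and dim probe sets collapse onto a floor. Its version and options are not given in the sources used here. The table held 31099 probe sets on 23 arrays, with values from 2.195 to 14.848. Array medians lay between 3.388 and 3.458, between 33.4% and 34.4% of probe sets lay at the floor of the scale on each array, and the mean correlation of an array with the others lay between 0.9959 and 0.9974. No array was a copy of another, with 0 identical pairs. Arrays give no read depth. Their number limits the precision, and a difference near the floor is compressed.

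The 57 control probe sets were left out of the comparisons, which left 31042. In the platform's annotation table, which predates the current gene table, 20826 of these named 1 gene, 436 named several and 9780 named none. Of those with 1 gene, 20758 were matched by gene identifier to a current rat gene table (assembly GRCr8), with 0 symbols changed, and genes are named by these symbols. Probe sets with several genes or none stayed in the counts and were never named. No genome coordinates were used. The names of some control rows and their values were out of register. The row named GAPDH 3' lay at 2.21, near the floor, the rows named GAPDH 5', GAPDH M and Hexokinase 3' followed probe sets of beta-actin (Actb) across the arrays with r of 0.93, 0.90 and 0.94, and the row named beta-actin 3' followed a Gapdh probe set with r of 0.84. The row named Hexokinase 5' followed Gapdh with r of 0.78 and Hk1 with 0.55, and Hexokinase M followed them with 0.60 and 0.23. Among the spiked controls, the CreX rows lay at 13.35 and 13.48 and the r2-P1-cre rows at 2.19, and the BioC rows lay at 8.45 and 8.05 and the r2-Ec-bioC rows at 2.19. The register of the gene probe sets was checked on 1000 pairs of the same gene, which had a median r of 0.36 against 0.02 for random pairs. The control rows were therefore used only as a gap on the log2 scale, the row named GAPDH 5' minus the row named GAPDH M, both of which followed Actb.

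Probe sets with a log2 value of at least 4 on at least 6 arrays were tested, 14647 in all. A linear model with 1 mean per group was fitted to all 23 arrays with limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0), with 20 residual and 2.35 prior degrees of freedom, and the moderated two-sided tests of lmFit and eBayes were adjusted by Benjamini-Hochberg over the tested probe sets of a comparison. A probe set was called changed at an adjusted p of at most 0.05. The comparisons were aged impaired against young, aged unimpaired against young, aged impaired against aged unimpaired, and the mean of both aged groups against young. A log2 difference is the first group minus the second, with the standard error (SE) of the fit, and group values are means with the standard deviation (SD). Where the mean of a group lay below a log2 value of 4, the fold is given as a bound against that level.

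A set of 37 gene lists, covering cell types, hippocampal fields next to CA3 and cellular functions, was written before the data were examined, and 940 of their 1058 entries had a probe set on the array. Each gene was represented by its brightest probe set, which gave 8726 genes, and the 36 lists with at least 3 measured genes were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The list of blood genes had 1 measured gene, Hbb. Camera was repeated with a correlation estimated per list, and fry, which asks whether a list's genes move on balance in 1 direction, was run beside it. Counts of list members that changed are given over all probe sets tested and adjusted over the list alone. Some genes stand on several lists. Genes named in the text were fixed by a rule: the 10 largest rises and 10 largest falls among called genes with a symbol in each of the 3 pairwise comparisons, up to 4 called members of each list by lowest p, or up to 2 by lowest p where none was called, and Gfap, Mbp, Aif1, Cldn5, Ttr, Grik4, Wfs1, Prox1, Gad1, Sst and Npy as markers.

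Both comparisons with young animals share the young arrays. Their overlap is given beside the mean of 100 simulations of unchanged aged groups against the same young arrays, the overlap of independent lists, and the overlap with the young animals divided into 5 with odd and 4 with even numbers. The fit was tested on simulated data made from the means and spreads of these probe sets, with independent noise. At each size 50 probe sets were changed. For aged impaired against aged unimpaired animals, 60% of probe sets changed by 1.25-fold, 92% of those changed by 1.5-fold and 98% of those changed by 2-fold were recovered, and 8 unchanged probe sets were called. For aged impaired against young animals the shares recovered were 62%, 88% and 96%, with 12 unchanged probe sets called, and for aged unimpaired against young animals 58%, 92% and 98%, with 12. A simulated list raised by 0.3 log2 units was called in each comparison, with 0 other lists. Simulated genes varied independently, unlike those of most real lists, so this cannot show how often correlated lists are called without a change. Random divisions of the real arrays called a median of 5 or 6 lists.

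The alternatives were no filter, a stricter filter on a mean log2 value of at least 6 (11140 probe sets), quantile normalization, centring of each array on its median, values below 4 set to 4, only the arrays of the groups compared, array weights, a prior variance with a trend and robust estimation, the replicate number as a block, the mean of a gene's probe sets, and each array left out in turn. A pair of alternatives was added after seeing the data: leaving out aged impaired arrays 1 and 2, which had the lowest array weights (0.47 and 0.52), and the gap between the control rows as a covariate. Correlations and group differences of single values were tested with exact two-sided permutation tests, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.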

Results

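RNA of the hippocampal CA3 field was profiled in 23 male Long-Evans rats with 1 microarray per animal. CA3 holds the pyramidal neurons that receive the mossy fibres of the dentate gyrus and excite one another through recurrent collaterals. Young rats were 6 months old (n = 9) and aged rats 24 to 26 months old. Learning was scored in the Morris water maze, where a rat learns the place of a hidden platform. The learning index of the aged unimpaired rats lay within the range of the young (n = 6), and that of the aged impaired rats was worse (n = 8). The values were log2 expression values of 14647 probe sets above a low filter. The question put to them was which transcripts change with age in CA3 and which of these changes go with the loss of spatial learning.

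In aged impaired against young animals, the 3 largest rises in log2 difference among called genes were those of Cd74, C3 and RT1-Da. Cd74, the invariant chain that chaperones MHC class II molecules, was at least 20-fold higher against a log2 level of 4, below which its young mean lay (log2 difference 4.38 ± 0.46 SE, limma adjusted p = 1.7e-05). Its group means were 8.32 ± 1.19 (SD, n = 8) and 3.94 ± 0.56 (SD, n = 9), with 8 of 8 aged impaired animals above every young animal. C3, the central component of the complement cascade, was at least 9.32-fold higher on the same terms (3.57 ± 0.38 SE, adjusted p = 1.7e-05), again in 8 of 8 animals. RT1-Da, an MHC class II chain that lay near the floor in young animals, was at least 2.38-fold higher (adjusted p = 0.0093), although its call ended when values below 4 were set to 4. The 10 largest rises also held Nat8f3 (3.89-fold), the matricellular protein Ccn2 (a log2 difference of 1.79), the inhibitory Fc receptor Fcgr2b (at least 2.41-fold), Gpnmb, a glycoprotein of phagocytic cells (3.08-fold), the calcium-binding S100a4 (2.93-fold), the C1 inhibitor Serping1 (2.93-fold) and the microsomal glutathione transferase Mgst1 (2.61-fold). Their adjusted p values ran from 7.65e-05 to 0.00381, with 6 to 8 of the 8 animals above every young animal.

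The falls were mostly smaller, and the largest, that of Rnf6, was uneven between animals. Rnf6, which encodes a RING-type ubiquitin ligase, was 6.36-fold lower (log2 difference -2.67 ± 0.58 SE, adjusted p = 0.00694). Its spread was wide in the aged impaired group (6.17 ± 2.07 SD, n = 8, against 8.84 ± 0.38 SD, n = 9), and 5 of 8 animals lay below every young animal. Ccer2 was at least 1.87-fold lower (-1.40 ± 0.25 SE, adjusted p = 0.00171) and the axon guidance ligand Sema3c 1.93-fold lower (-0.95 ± 0.15 SE, adjusted p = 0.000673), with 5 and 7 of 8 animals below every young animal. Hcrt, the precursor of the orexin peptides, was 2.22-fold lower, the glycine receptor subunit Glra2 1.91-fold, the receptor phosphatase Ptpro 1.63-fold, the thyrotropin-releasing hormone degrading enzyme Trhde 1.56-fold, the Na,K-ATPase regulator Fxyd7 1.54-fold, Plcxd2 1.54-fold and the somatostatin receptor Sstr2 1.51-fold. Their adjusted p values ran from 0.0124 to 0.0402, and for each 3 to 6 of 8 animals lay below every young animal. The calls of Hcrt, Glra2, Ptpro and Plcxd2 ended when no filter was applied, which raises the number of tests.

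**Figure D1:**
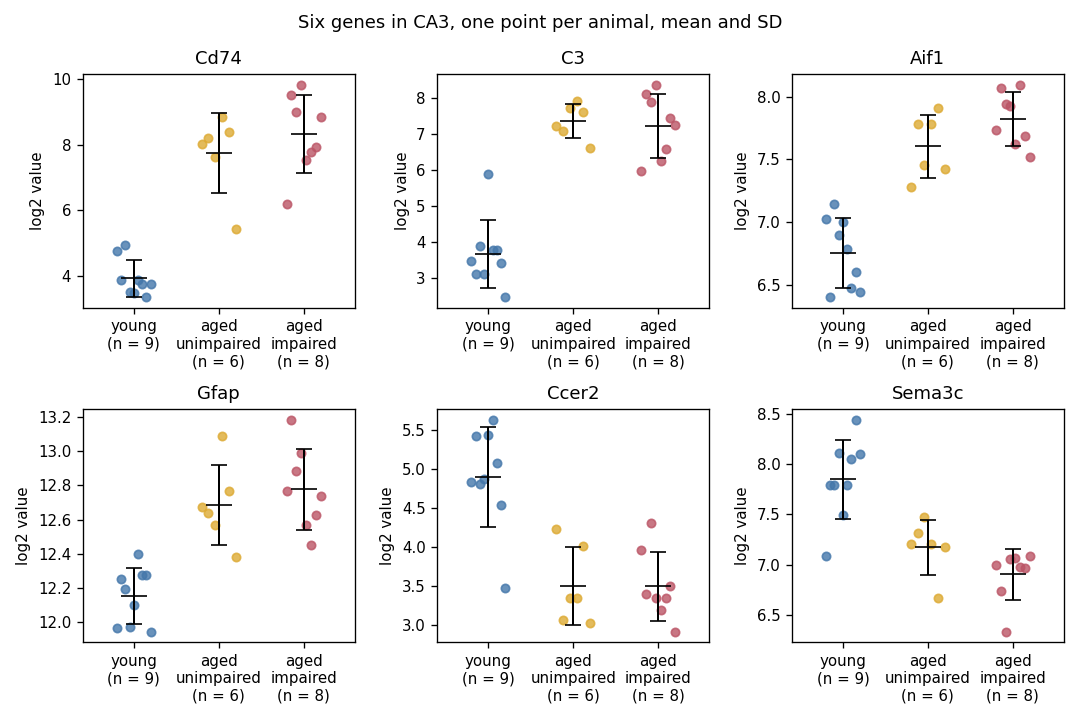
Log2 expression values (y axis) of Cd74, C3, Aif1, Gfap, Ccer2 and Sema3c in young, aged unimpaired and aged impaired animals (x axis), 1 point per animal, with the mean and SD of each group as bars. For Cd74, C3 and Aif1 all 8 aged impaired and all 6 aged unimpaired animals lie above every young animal, whereas Ccer2 and Sema3c are lower in aged animals with some overlap.

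Glial and immune lists moved together in aged impaired animals. Of 13 measured microglial genes, 11 rose (12 adjusted over the list alone). The list stood above other genes with a median log2 difference of 0.71 (camera adjusted p = 5.74e-19, and adjusted p = 0.0209 with an estimated correlation). The calcium-binding protein Aif1 rose 2.1-fold (1.07 ± 0.12 SE), the Fc receptor chain Fcer1g 1.89-fold, the purinergic receptor P2ry12 1.64-fold and the growth factor receptor Csf1r 1.49-fold, each in 8 of 8 animals above every young animal. Of 12 reactive glia genes, 10 rose (11 adjusted over the list alone), with a median of 0.69 (adjusted p = 9.58e-14, and adjusted p = 0.0489 with an estimated correlation). Among them were the intermediate filaments Vim (1.76-fold) and Gfap (1.54-fold) and the annexin Anxa3 (1.63-fold). Of 8 complement genes, 6 rose (7 adjusted over the list alone), with a median of 0.59 (adjusted p = 2.85e-09, and adjusted p = 0.0425 with an estimated correlation). They included C3, Serping1, the initiating subunit C1qa (1.69-fold) and the protease C1s (1.56-fold). These were the 3 lists whose camera call also held with an estimated correlation in this comparison.

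Further lists were higher with the preset correlation alone. Of 10 antigen presentation genes, 4 rose (4 adjusted over the list alone): Cd74, RT1-Da, the MHC class I light chain B2m (1.31-fold) and the proteasome activator Psme1 (1.34-fold). The list's median was 0.20 (camera adjusted p = 2.37e-05, and adjusted p = 0.14 with an estimated correlation). Of 6 interferon response genes, Ifitm3 (1.75-fold) and Irf9 (1.47-fold) rose (2 adjusted over the list alone). The median was 0.26 (adjusted p = 0.013, and adjusted p = 0.226 with an estimated correlation). Of 18 astrocyte genes, 6 rose (8 adjusted over the list alone), including Gfap, the calcium-binding S100b (1.16-fold) and the membrane protein Mlc1 (1.26-fold). The median was 0.14 (adjusted p = 5e-05, and adjusted p = 0.394 with an estimated correlation). Of 37 lysosome and autophagy genes, 9 rose and 2 fell (15 and 4 adjusted over the list alone), led by the protease Ctsz (2.56-fold), the cholesterol carrier Npc2 (1.61-fold) and the membrane proteins Lamp2 (1.45-fold) and Cd63 (1.33-fold). The median was 0.08 (adjusted p = 6.03e-05, and adjusted p = 0.345 with an estimated correlation). The antioxidant list had 4 of 28 genes that rose (4 adjusted over the list alone), led by the glutathione transferase Gstp1 (1.48-fold) and the transcription factor Nfe2l2 (1.28-fold). Its median was 0.02 (adjusted p = 0.0176, and adjusted p = 0.626 with an estimated correlation).

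On the glucocorticoid response list, the 2 of 22 genes that rose (2 adjusted over the list alone) were Mt2A, a metallothionein that binds metals (1.49-fold), and Mertk, a receptor for the uptake of apoptotic cells (1.30-fold). The list's median was 0.07 (adjusted p = 0.0149, and adjusted p = 0.533 with an estimated correlation), and the calls of both genes ended when no filter was applied. Of 20 oligodendrocyte and myelin genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone). Those that rose were Plekhb1 (1.28-fold), the pterin reductase Qdpr (1.29-fold) and the lipocalin Apod (1.32-fold), none of which is a structural myelin protein, and the galactolipid enzyme Ugt8 was 1.39-fold lower. The list's median was 0.07 (adjusted p = 0.0107, and adjusted p = 0.651 with an estimated correlation). Of 9 oligodendrocyte precursor genes, Bcas1 rose (1.31-fold; 1 adjusted over the list alone), and the median was 0.09 (adjusted p = 0.0128, and adjusted p = 0.255 with an estimated correlation).

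The CA3 marker, heat shock, calcium and oxidative phosphorylation lists were lower in aged impaired animals, by small amounts and with the preset correlation alone. Of 15 CA3 marker genes, Nrip3 (1.23-fold), the secreted protein Dkk3 (1.15-fold), the granin Chgb (1.18-fold) and the kainate receptor subunit Grik5 (1.16-fold) fell (7 adjusted over the list alone). The list's median was -0.18 (adjusted p = 0.00152, and adjusted p = 0.345 with an estimated correlation). On the same arrays the list of 10 CA1 markers was higher, with a median of 0.26 (adjusted p = 0.0226, and adjusted p = 0.553 with an estimated correlation), although 0 of its genes passed (0 adjusted over the list alone). Per animal, the CA3 marker score was -0.12 ± 0.15 (SD) in aged impaired, 0.01 ± 0.19 in aged unimpaired and 0.10 ± 0.18 in young animals. The CA1 marker score was 0.14 ± 0.40, -0.01 ± 0.18 and -0.12 ± 0.42, with young 4 at -1.06, and without that array the CA1 list's median was 0.12 and its call ended. Of 29 heat shock and chaperone genes, 8 fell and 2 rose (16 and 2 adjusted over the list alone). The HSP90 cofactors Chordc1 (1.31-fold), Ahsa1 (1.15-fold) and Stip1 (1.14-fold) and the HSP40 Dnaja1 (1.17-fold) were lower. The list's median was -0.11 (adjusted p = 0.00018, and adjusted p = 0.345 with an estimated correlation).

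Of 37 calcium channel and calcium signalling genes, 9 fell and 1 rose (14 and 1 adjusted over the list alone). Among the falls were the N-type channel pore Cacna1b (1.16-fold) and the auxiliary subunits Cacnb3 (1.21-fold) and Cacna2d3 (1.14-fold), and the median was -0.11 (adjusted p = 0.0059, and adjusted p = 0.533 with an estimated correlation). Of 68 oxidative phosphorylation genes, 4 fell (1 adjusted over the list alone), namely Ndufb6 of complex I and Uqcr11, Uqcrc2 and Uqcrfs1 of complex III (1.09-fold to 1.12-fold). The median was -0.05 (adjusted p = 0.0131, and adjusted p = 0.767 with an estimated correlation). The camera call of this list ended with quantile normalization, that of the CA1 list with array weights, and those of the glucocorticoid and antioxidant lists without aged impaired arrays 1 and 2.

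Other lists held changed genes without a camera call. With fry, which tests a list without comparing it with other genes, 14 lists passed in this comparison. Of those without a camera call, the neurogenesis (fry adjusted p = 0.00599), potassium channel (0.0111) and synaptic vesicle (0.0488) lists passed fry, all downward. Of those with a camera call, the oligodendrocyte (0.29), glucocorticoid (0.18), antioxidant (0.287), CA1 (0.229) and oxidative phosphorylation (0.229) lists did not. Among synaptic vesicle genes 5 of 29 fell (7 adjusted over the list alone; list adjusted p = 0.0763), including synapsin Syn1 (1.16-fold) and neurexin Nrxn2 (1.16-fold). Among potassium and HCN channel genes 5 of 28 fell (5 adjusted over the list alone; list adjusted p = 0.342), led by Dpp6 (1.17-fold, in 8 of 8 animals below every young animal), whose other probe set stood at 0.07. Of 28 glutamate receptor and postsynaptic genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone; list adjusted p = 0.805). Cacng2, an AMPA receptor auxiliary subunit, was 1.36-fold lower and the metabotropic receptor Grm3 1.31-fold higher. On the GABA receptor list 2 of 9 fell (2 adjusted over the list alone; list adjusted p = 0.533), with Gabra5 1.12-fold and Gabbr2 1.19-fold lower. Of 15 neurogenesis and immature neuron genes, the tubulins Tubb2b (1.28-fold) and Tubb3 (1.12-fold) and the growth-cone protein Gap43 (1.18-fold) fell (4 adjusted over the list alone; list adjusted p = 0.327). Of 26 immediate early genes, Nr4a3 fell 1.40-fold (1 adjusted over the list alone; list adjusted p = 0.805).

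The clock list had 3 rises and 3 falls among 17 genes (3 and 3 adjusted over the list alone; list adjusted p = 0.0763). The repressors Bhlhe40 (2.29-fold) and Bhlhe41 (1.46-fold) were higher and Tef 1.23-fold lower, while another probe set of Tef stood at 0.35. Of 27 endoplasmic reticulum stress genes, 4 fell (6 falls and 1 rise adjusted over the list alone; list adjusted p = 0.27), including Manf (-0.32 ± 0.07 SE) and the chaperone Hspa5 (1.21-fold). The glycolysis list had 2 falls in 23 (3 rises and 4 falls adjusted over the list alone; list adjusted p = 0.597), with Ldha 1.10-fold lower. Cholesterol synthesis had 2 falls in 20 (2 adjusted over the list alone; list adjusted p = 0.367), with Sqle 1.16-fold lower. The growth factor and neuropeptide list had 3 falls in 20 (1 rise and 3 falls adjusted over the list alone; list adjusted p = 0.386), with Nptx1 1.15-fold lower. The hypoxia list had 1 rise and 3 falls in 21 (4 and 5 adjusted over the list alone; list adjusted p = 0.963), with Hilpda 1.26-fold lower. On the proteasome list 0 of 32 genes passed (0 adjusted over the list alone; list adjusted p = 0.0673), and Psmb5 stood at -0.11 ± 0.04 SE. On the senescence and DNA damage list 0 of 15 passed (2 rises adjusted over the list alone; list adjusted p = 0.533), and Gadd45b stood at 0.48 ± 0.16 SE.

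The endothelial, meningeal, choroid plexus, dentate gyrus, interneuron and CA2 lists did not pass in this comparison. The medians were 0.05 for 12 endothelial and pericyte genes (0 changed, 0 adjusted over the list alone; list adjusted p = 0.342) and 0.08 for 7 meningeal and fibroblast genes (0 and 0 adjusted over the list alone; list adjusted p = 0.597). They were 0.03 for 3 choroid plexus genes (0 and 1 fall adjusted over the list alone; list adjusted p = 0.805) and 0.05 for 11 dentate gyrus genes (0 and 0 adjusted over the list alone; list adjusted p = 0.597). For 16 interneuron genes the median was -0.02 (0 and 0 adjusted over the list alone; list adjusted p = 0.762). Of 7 CA2 genes, Pcp4 and Rgs14 fell (2 adjusted over the list alone; median -0.09, list adjusted p = 0.342). The blood marker Hbb stood at 0.22 ± 0.21 SE. The myelin marker Mbp stood at 0.03 ± 0.04, the endothelial Cldn5 at 0.01 ± 0.07 and the choroid plexus marker Ttr at 0.03 ± 0.38. The CA3 marker Grik4 stood at -0.18 ± 0.07, the CA1 marker Wfs1 at 0.48 ± 0.29, the dentate marker Prox1 at -0.17 ± 0.21, and the interneuron markers Gad1, Sst and Npy at -0.01 ± 0.09, 0.15 ± 0.14 and -0.08 ± 0.11, none of which passed. Median and mean differed in sign for the meningeal list (0.08 and -0.06, test upward), the choroid plexus list (0.03 and -0.06, test downward) and the senescence list (-0.04 and 0.04, test upward). The interneuron list (median -0.02, mean -0.01) and the immediate early list (-0.02 and -0.01) were placed upward by the test, and the glutamate receptor list had a median of 0.00 and a mean of 0.02.

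In total 1429 of 14647 probe sets passed in aged impaired against young animals, 568 higher and 861 lower, covering 395 and 638 named genes. Rises were the larger changes, with a median log2 difference of 0.38 against -0.22 for the falls, and at a log2 difference of at least 1 there were 28 rises and 3 falls. The share of higher calls was 39.7%, and 50% with each array centred on its median (768 higher and 768 lower). It was 28.8% without aged impaired array 1 (520 higher and 1288 lower), 26.7% without arrays 1 and 2 (417 and 1147) and 50.4% without array 7 (645 and 634). The count was 768 without the filter and 937 with the gap between the control rows as a covariate.

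The second comparison asked what aged animals with intact learning shared with or lacked from this picture. In aged unimpaired against young animals, C3 rose at least 10.2-fold (log2 difference 3.70 ± 0.41 SE, adjusted p = 7.56e-05) and Cd74 at least 13.5-fold (3.81 ± 0.50 SE, adjusted p = 0.000304), with 6 of 6 aged unimpaired animals above every young animal for both. The rises of Fcgr2b (at least 2.62-fold), Nat8f3 (3.37-fold), the ceramidase Acer2 (at least 1.64-fold), Ccn2 (2.78-fold), Mgst1 (2.66-fold), Ctsz (2.38-fold) and Gpnmb (2.34-fold) had adjusted p values from 0.00151 to 0.0448. For each, 5 or 6 of 6 animals lay above every young animal. Scgb1d4, a secretoglobin, lay at the floor in all 9 young animals and on average at 5.32 ± 2.46 (SD, n = 6) in aged unimpaired animals. The rise was at least 2.5-fold (limma adjusted p = 0.0446), and 4 of 6 animals exceeded a log2 value of 4. High values were not limited to this group, since Scgb1d4 stood at 6.37 and 5.92 on aged impaired arrays 3 and 5. Its probe set met the filter only with those arrays counted. The calls of Acer2, Ccn2 and Scgb1d4 ended when no filter was applied.

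Ccer2 was at least 1.87-fold lower (-1.40 ± 0.27 SE, adjusted p = 0.00833), the A-type potassium channel Kcnd2 1.77-fold, Ptpro 1.76-fold, Ildr2 1.71-fold and the splicing regulator Tra2a 1.70-fold. Also lower were the P/Q-type calcium channel pore Cacna1a 1.62-fold, Sema3c 1.60-fold, the muscarinic receptor Chrm3 1.57-fold, the syntaxin Stx1a 1.53-fold and Pigt 1.52-fold. Their adjusted p values ran from 0.00612 to 0.0427, and 0 to 5 of 6 animals lay below every young animal. For Kcnd2, Ildr2, Tra2a, Cacna1a, Stx1a and Pigt the probe set named was the lowest of 2 or more of the gene, and the highest stood at -0.27, 0.00, -0.11, -0.28, -0.25 and -0.19. Of these falls, those of Kcnd2, Ptpro, Ildr2, Cacna1a, Sema3c, Stx1a and Pigt were no longer called when no filter was applied.

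Microglial genes again led the lists. Of 13 measured, 10 rose (13 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 6.05e-17, and adjusted p = 0.0353 with an estimated correlation). They included Aif1 (1.81-fold), Fcer1g (1.69-fold) and P2ry12 (1.63-fold), each in 6 of 6 animals. This was the 1 list whose call held with an estimated correlation. Of 12 reactive glia genes, 6 rose (11 adjusted over the list alone; median 0.55, adjusted p = 5.02e-10, and adjusted p = 0.138 with an estimated correlation). Among them were Gfap (1.45-fold), Anxa3 (1.5-fold) and the protease inhibitor A2m (1.66-fold). Of 8 complement genes, C3, C1qa (1.77-fold) and C1s (1.48-fold) rose (7 adjusted over the list alone). The median was 0.53 (adjusted p = 3.49e-08, and adjusted p = 0.0705 with an estimated correlation). The antigen presentation list had 3 rises in 10, Cd74, B2m (1.24-fold) and Psme1 (1.26-fold) (4 adjusted over the list alone). Its median was 0.28 (adjusted p = 1.79e-05, and adjusted p = 0.138 with an estimated correlation). Of 18 astrocyte genes, Gfap, S100b (1.15-fold), Slc4a4 (1.18-fold) and Acsbg1 (1.22-fold) rose (7 adjusted over the list alone). The median was 0.19 (adjusted p = 2.95e-06, and adjusted p = 0.368 with an estimated correlation).

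The lysosome list had 3 rises in 37, Ctsz, Npc2 (1.52-fold) and Ctsh (1.28-fold) (11 adjusted over the list alone). Its median was 0.07 (adjusted p = 0.00261, and adjusted p = 0.49 with an estimated correlation). On the glucocorticoid list Mertk was 1.40-fold higher (2 adjusted over the list alone; median 0.11, adjusted p = 0.00261, and adjusted p = 0.376 with an estimated correlation). On the interferon list Ifitm3 was 1.5-fold higher (2 adjusted over the list alone; median 0.34, adjusted p = 0.0182, and adjusted p = 0.23 with an estimated correlation). Gstp1 (1.32-fold) and Nfe2l2 (1.39-fold) rose on the antioxidant list (4 adjusted over the list alone). Its median was 0.06 (adjusted p = 0.0287, and adjusted p = 0.645 with an estimated correlation).

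Lists that were lower in aged unimpaired animals held few called genes. On the synaptic vesicle list the vesicular glutamate transporter Slc17a7 fell 1.36-fold (4 adjusted over the list alone; median -0.06, adjusted p = 0.00139, and adjusted p = 0.376 with an estimated correlation). On the neurogenesis list Tubb2b fell 1.17-fold (6 adjusted over the list alone; median -0.08, adjusted p = 0.039, and adjusted p = 0.23 with an estimated correlation). On the CA3 list 0 members passed (0 adjusted over the list alone; median -0.12, adjusted p = 0.00601, and adjusted p = 0.409 with an estimated correlation), with Grik5 at -0.22 ± 0.07 SE. On the calcium list 0 passed (2 falls adjusted over the list alone; median -0.04, adjusted p = 0.00743, and adjusted p = 0.512 with an estimated correlation), with Cacna1b at -0.18 ± 0.05 SE. On the proteasome list 0 passed (0 adjusted over the list alone; median -0.04, adjusted p = 0.0112, and adjusted p = 0.716 with an estimated correlation). The glutamate receptor list (0 changed, 0 adjusted over the list alone, median -0.08) had adjusted p = 0.039, and adjusted p = 0.451 with an estimated correlation. The oxidative phosphorylation list (0 changed, 0 adjusted over the list alone, median -0.02) had adjusted p = 0.0491, and adjusted p = 0.903 with an estimated correlation. On the heat shock list the small heat shock protein Hspb8 rose 1.54-fold (2 rises and 3 falls adjusted over the list alone). The test of that list was downward, with a median of -0.07 and a mean of 0.01 (adjusted p = 0.0182, and adjusted p = 0.564 with an estimated correlation). With quantile normalization the calls of the glutamate receptor, neurogenesis and oxidative phosphorylation lists ended, as did that of the interferon list without the filter and that of the antioxidant list with array weights. With fry 7 lists passed, those of microglia, reactive glia, complement, antigen presentation, interferon response, astrocytes and, downward, neurogenesis.

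On lists without a camera call, the sphingolipid hydroxylase Fa2h (1.5-fold) and the myelin proteolipid Mal (1.37-fold) fell and Plekhb1 rose 1.22-fold on the myelin list (2 rises and 3 falls adjusted over the list alone; list adjusted p = 0.522). The CA2 marker Amigo2 rose 1.53-fold (1 rise and 1 fall adjusted over the list alone; list adjusted p = 0.954), and the kinase Pdk1 rose 1.46-fold on the glycolysis list (1 adjusted over the list alone; list adjusted p = 0.937). On the cholesterol list Sc5d rose 1.23-fold and Cyp51 fell 1.19-fold (1 and 2 adjusted over the list alone; list adjusted p = 0.421). The transcription factor subunit Jun fell 1.37-fold among immediate early genes (1 rise and 1 fall adjusted over the list alone; list adjusted p = 0.472). Hbb stood at -0.16 ± 0.22 SE. The count of this comparison was 302 probe sets, 200 higher and 102 lower, covering 139 and 82 named genes, with 18 rises and 2 falls of at least 1 on the log2 scale. The split moved to 375 higher and 297 lower with array weights, to 196 and 186 without aged unimpaired array 7 and to 128 and 47 without aged unimpaired array 4. Without the filter the count was 126 and with array weights 672. It was 175, 184 or 196 without aged unimpaired array 4, aged unimpaired array 6 or young array 3.

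**Figure D2:**
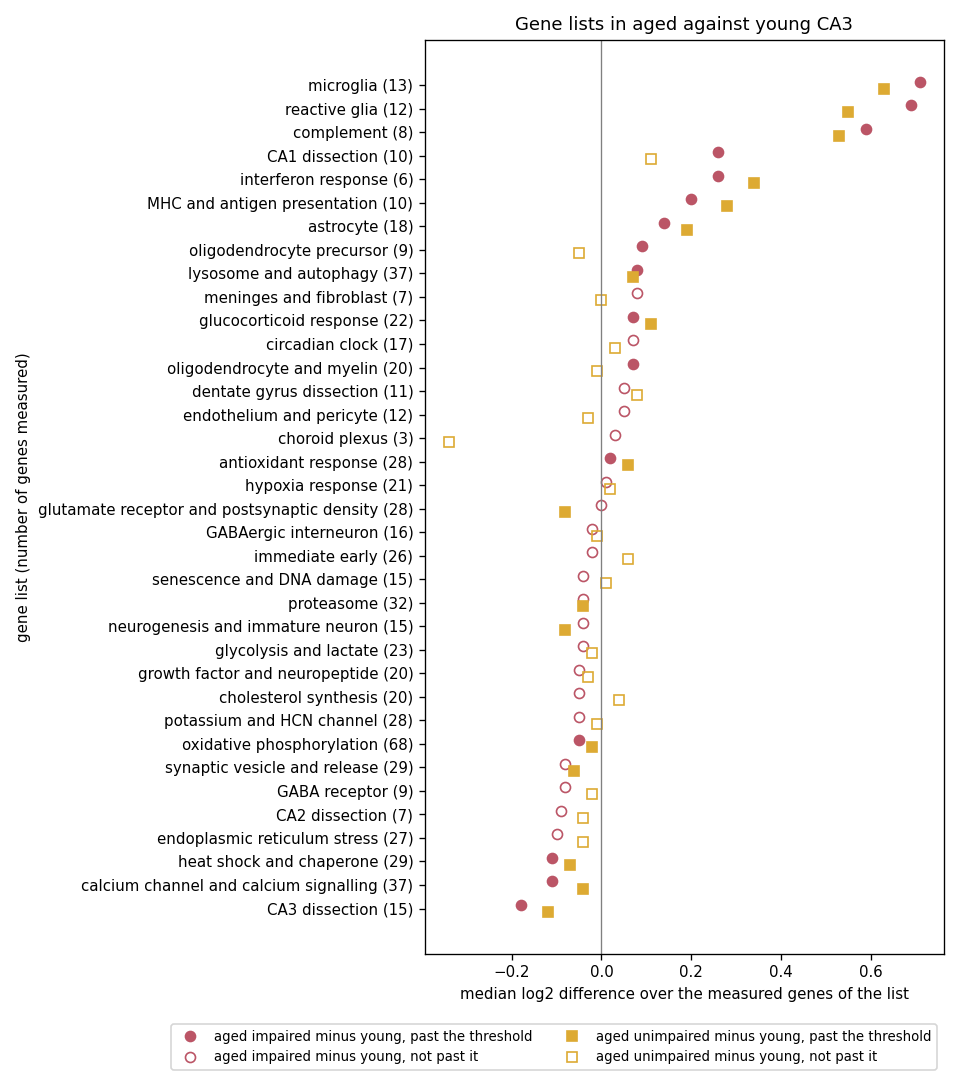
Median log2 difference (x axis) over the measured genes of each list (y axis, with their number) for aged impaired minus young (circles) and aged unimpaired minus young (squares), with filled symbols where camera with the preset correlation passed. The microglia, reactive glia and complement lists lie farthest to the right in both comparisons, at 0.71, 0.69 and 0.59 and at 0.63, 0.55 and 0.53.

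Between the comparisons with young animals, 131 probe sets were higher in both, 48 were lower in both and 0 went opposite ways. Because the young arrays are shared, some overlap arises without any effect: simulated unchanged aged groups gave a mean of 1.28 higher and 2.83 lower in both, with at most 43 and 132 in a single draw, and independent lists of these sizes would share 7.756 and 5.996. With the young animals divided between the comparisons, 31 or 38 probe sets were higher in both and 7 or 7 lower in both. Across probe sets, which are not independent replicates, the log2 differences correlated with r = 0.549 against a mean of 0.430 in the simulation, inside its range of 0.107 to 0.792. Their covariance was 0.01816 against a simulated mean of 0.004487 and a highest draw of 0.01763. With both aged groups averaged, 1010 probe sets differed from young, 489 higher and 521 lower, and 15 lists passed camera. The microglia list (11 of 13 rose, 13 adjusted over the list alone, adjusted p = 0.0166 with an estimated correlation) and the complement list (7 of 8 rose, 7 adjusted over the list alone, adjusted p = 0.0361 with an estimated correlation) held with an estimated correlation.

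The last comparison, between the aged groups, asked which transcripts go with the loss of learning at the same age. The largest called differences were higher values of single probe sets in aged impaired animals, and the lower values were smaller. Setd5, a SET-domain chromatin protein, was 3.33-fold higher (log2 difference 1.74 ± 0.25 SE, adjusted p = 0.00654). Its means were 6.32 ± 0.47 (SD, n = 8) and 4.58 ± 0.70 (SD, n = 6), with 7 of 8 aged impaired animals above every aged unimpaired animal. The ubiquitin ligase Herc1 was 3.35-fold higher, the RNA helicase Ddx6 2.87-fold, Pnma8b 2.35-fold, the elongation factor scaffold Aff4 2.34-fold, and the cohesin loader Nipbl 2.15-fold. Also higher were the taurine transporter Slc6a6 at least 1.41-fold, the kinesin Kif5c 2.07-fold, the sorting protein Pacs2 2.05-fold and the neuronal calcium sensor Hpcal4 2.05-fold. The adjusted p values of these genes ran from 0.0238 to 0.0418. For Hpcal4 8 of 8 aged impaired animals lay above every aged unimpaired animal, and for the others 2 to 7 did.

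Other probe sets of the same genes mostly stood closer to 0. Those of Setd5, Ddx6, Aff4, Nipbl, Kif5c and Pacs2 stood at 0.03, -0.02, -0.03, 0.06, 0.07 and 0.07, whereas that of Slc6a6 stood at 0.20, that of Pnma8b at 0.55 and those of Hpcal4 at -0.02 and 0.65. Herc1 had no other probe set past the filter. The gap between the control rows that follow beta-actin was 2.14 ± 0.09 (SD, n = 8) in aged impaired and 2.28 ± 0.09 (SD, n = 6) in aged unimpaired animals. The difference was -0.14 (exact permutation p = 0.0153, two-sided, adjusted p = 0.046 over 3 group pairs). Of the 99 probe sets higher in aged impaired animals, 44 were also higher in aged impaired than in young animals, and 9 were lower in aged unimpaired than in young animals.

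Lower in aged impaired animals were Amigo2, an adhesion molecule and CA2 marker (1.51-fold, log2 difference -0.60 ± 0.14 SE, adjusted p = 0.0489), the isoprenoid enzyme Idi1 (1.34-fold) and the sterol desaturase Sc5d (1.28-fold). Tank, a regulator of NF-kB signalling, was 1.33-fold lower, Rerg 1.29-fold, the HSP90 cofactor Chordc1 1.26-fold, Cmip by 0.32 on the log2 scale, the initiation factor Eif1a 1.23-fold, the mitochondrial transport adaptor Trak1 1.21-fold and the folliculin partner Fnip1 1.19-fold. The adjusted p values of these 9 genes beside Amigo2 ran from 0.0238 to 0.0489. For Rerg, Sc5d, Cmip and Fnip1 8 of 8 aged impaired animals lay below every aged unimpaired animal. Of the 15 probe sets lower in aged impaired animals, 8 were also lower and 1, of Fnip1, was higher in aged impaired than in young animals. The 3 that were higher in aged unimpaired than in young animals were those of Amigo2 (0.61 ± 0.14 SE), Fnip1 (0.42 ± 0.05 SE) and Sc5d (0.30 ± 0.07 SE).

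**Figure D3:**
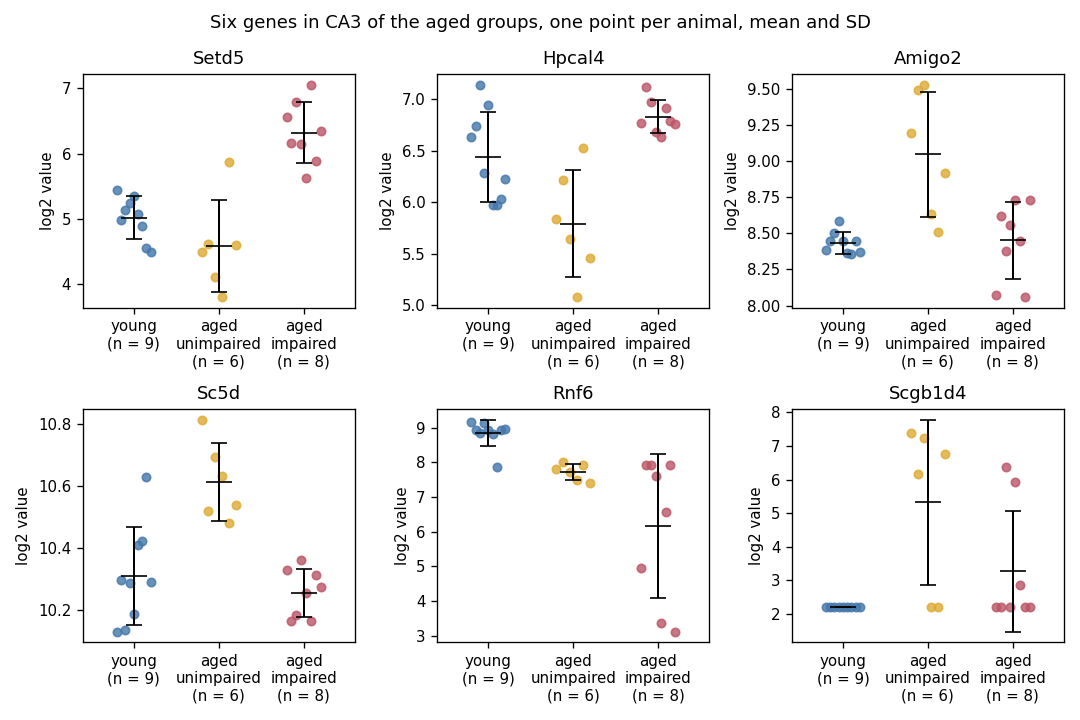
Log2 expression values (y axis) of Setd5, Hpcal4, Amigo2, Sc5d, Rnf6 and Scgb1d4 in young, aged unimpaired and aged impaired animals (x axis), 1 point per animal, with the mean and SD of each group as bars. Setd5 and Hpcal4 are higher and Amigo2 and Sc5d lower in aged impaired than in aged unimpaired animals, while Rnf6 and Scgb1d4 were called only against young animals and vary widely within an aged group.

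Of the 10 largest rises and 10 largest falls in either comparison with young animals, Kcnd2 alone passed between the aged groups, with a higher value in aged impaired animals (0.90 ± 0.21 SE, adjusted p = 0.0435). The other probe set of Kcnd2 stood at 0.22. Cd74 stood at 0.57 ± 0.51 SE (adjusted p = 0.655), Aif1 at 0.22 ± 0.13 SE (adjusted p = 0.451) and Gfap at 0.09 ± 0.11 SE (adjusted p = 0.759). Camera placed 5 lists higher in aged impaired animals, and 0 held with an estimated correlation or passed fry (1 and 3 at an unadjusted p under 0.05). On the oligodendrocyte list 0 of 20 genes passed (1 adjusted over the list alone; median 0.12, adjusted p = 5.14e-06, and adjusted p = 0.819 with an estimated correlation), with Fa2h at 0.39 ± 0.11 SE. On the precursor list 0 of 9 passed (0 adjusted over the list alone; median 0.06, adjusted p = 0.00419, and adjusted p = 0.43 with an estimated correlation), with Tnr at 0.75 ± 0.29 SE. The reactive glia list had 0 of 12 (0 adjusted over the list alone; median 0.11, adjusted p = 0.0116, and adjusted p = 0.819 with an estimated correlation). The microglia list had 0 of 13 (0 adjusted over the list alone; median 0.12, adjusted p = 0.0243, and adjusted p = 0.819 with an estimated correlation). On the glutamate receptor list Grm3 was 1.37-fold higher (3 adjusted over the list alone; median 0.00, mean 0.09, adjusted p = 0.0304, and adjusted p = 0.819 with an estimated correlation). The calls of the microglia and glutamate receptor lists ended without the filter, and those lists and the reactive glia list lost their calls with the gap as a covariate. The complexin Cplx2, on the synaptic vesicle list, was 1.71-fold higher (3 rises and 1 fall adjusted over the list alone; list adjusted p = 0.314). On the cholesterol synthesis list Sc5d and Idi1 fell (4 adjusted over the list alone; list adjusted p = 0.0604), and on the heat shock list Chordc1 fell (1 adjusted over the list alone; list adjusted p = 0.0526). The CA3 and CA1 marker lists had medians of -0.06 (adjusted p = 0.47) and 0.14 (adjusted p = 0.0658).

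The count between the aged groups was 114 probe sets, 99 higher and 15 lower in aged impaired animals, covering 75 and 12 named genes, with 17 rises and 0 falls of at least 1 on the log2 scale. limma called 0 with only the arrays of both aged groups in the fit (2049 at an unadjusted p under 0.05) and 0 with the gap as a covariate (1275 at an unadjusted p under 0.05), 2 without the filter and 4 without aged impaired arrays 1 and 2. The median difference of the 99 probe sets was 0.66 (median SE 0.14). It was also 0.66 (median SE 0.15) both with only those arrays and without the filter. These settings leave the group means as they are, so the difference could not change there and says nothing of how firm it is. With the gap as a covariate, which can change it, it was 0.49 (median SE 0.15). Leaving out single arrays gave counts from 2 (without aged unimpaired array 4) to 447 (without aged unimpaired array 7). On the first principal component aged unimpaired 7 stood at -8.72, within the range of the aged impaired animals (-22.77 to -5.60), and the other aged unimpaired animals stood from -1.92 to 7.71.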

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

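The tests of RNA integrity, of the whole transcript, of a lower share of CA3 neurons, of blood or meninges and of an allele, and the alternatives that left out aged impaired arrays 1 and 2 or used the gap as a covariate, were chosen only after the result was seen.

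Chance was examined by dividing the arrays into groups of the same sizes in 100 ways, the real division included. For the number of changed probe sets, 1 of 100 divisions, the real one, gave as many in each comparison: aged impaired against young 1429 with 1 as the highest other, aged unimpaired against young 302 with 9, aged impaired against aged unimpaired 114 with 2, and both aged groups against young 1010 with 3. Chance could be excluded for these counts in the comparisons with young animals. Between the aged groups, leaving out 1 array gave 2 to 447 probe sets. The lowest of these equals the highest other division, so chance is not firmly excluded for the count of 114. Gene lists were often called in the other divisions, with a median of 5, 6, 5 and 6 lists in the same order. For the 17 lists of aged unimpaired against young animals it was 1 of 100, with 13 as the highest other. Since leaving out 1 array gave 13 to 17 lists in that comparison, chance is not firmly excluded for its count. For the 16 lists of aged impaired against young it was also 1 of 100, but by a narrow margin, with 15 as the highest other. Leaving out 1 array gave 14 to 18 lists there, so chance is not firmly excluded for that count. Chance could not be excluded for the 5 lists between the aged groups, which 56 of 100 divisions matched, with 19 as the highest other. Nor could it for the 15 lists of both aged groups against young, which 5 of 100 matched, with 18.

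The change against young differed between the aged groups for 114 probe sets, tested as aged impaired minus aged unimpaired animals in the shared fit. Among the genes named for this comparison the difference was 1.75 for Herc1, 1.74 for Setd5, 1.52 for Ddx6, 1.24 for Pnma8b, 1.22 for Aff4, 1.10 for Nipbl, 1.09 for Slc6a6, 1.05 for Kif5c, 1.04 for Pacs2, 1.04 for Hpcal4, 0.77 for Cplx2 and 0.46 for Grm3. It was -0.60 for Amigo2, -0.42 for Idi1, -0.41 for Tank, -0.37 for Rerg, -0.36 for Sc5d, -0.33 for Chordc1, -0.32 for Cmip, -0.30 for Eif1a, -0.27 for Trak1 and -0.25 for Fnip1. Outside the measured genes, the gap between the control rows differed by -0.14 between aged impaired and aged unimpaired animals, and the control row named GAPDH 5' followed a probe set of Actb with r = 0.93.

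The first pattern weighed is the set of 99 probe sets with higher values in aged impaired than in aged unimpaired animals. A change of each gene's whole transcript by as much as the called probe sets was argued against. The other probe sets of 61 of the 75 genes had a median difference of 0.02 against 0.63 for the called ones. The called ones were chosen by this contrast, which raises their value, so calls raised by selection stay open. The 2 aged impaired arrays of lowest weight also stay open as a source. Without both the median difference was 0.63, but most calls ended. These probe sets were chosen by a test that favours differences shared by all arrays, so that median cannot decide it. RNA integrity or labelling stays open and cannot be told apart from the groups: r between the mean of these probe sets and the gap was -0.39 over the 9 young arrays (exact permutation p = 0.314), -0.45 over the 8 aged impaired arrays (p = 0.263) and -0.92 over the 6 aged unimpaired arrays (p = 0.0222), with adjusted p of 0.314, 0.314 and 0.0667 over the 3 groups, and with the 2 arrays farthest out removed r was 0.12, -0.35 and -0.35. With the gap as a covariate the call of each of these probe sets ended, as their median difference fell from 0.66 (median SE 0.14) to 0.49 (median SE 0.15), a smaller difference with a slightly larger error. Learning status also stays open, untested apart from the gap, which differed between the same groups and whose reading as RNA integrity is uncertain, since its rows are misnamed.

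The second pattern is the higher level of microglia and complement genes in both aged groups. A lower share of CA3 neurons in the aged samples would raise the markers of other cell types alike. It was argued against as the whole source, since the highest median of the endothelium and oligodendrocyte lists came to 9.9% of the microglia median. As a part of the source it stays open. Against young animals the astrocyte list had medians of 0.14 (aged impaired) and 0.19 (aged unimpaired), and the CA3 marker list -0.18 and -0.12. A trend with the gap was argued against as the whole source, since at least 99.4% of the microglia median was kept with the gap as a covariate, but the rows of the gap are misnamed, so how far it measures RNA integrity is not known and integrity apart from the gap stays open. Blood or meninges left on the aged samples stay open, since the meninges list had medians of 0.08 and 0.00 with members on both sides and Hbb stood at 0.22 ± 0.21 SE and -0.16 ± 0.22 SE. The comparisons with young animals tested the difference between ages but not its cause, so age itself, which the design names, stays open as the source. More microglia cannot be told apart from more transcript per cell in bulk tissue.

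The third pattern is Rnf6, which stood at 3.11, 3.37 and 4.95 on aged impaired arrays 8, 5 and 1 against a median of 7.93 over the arrays of all groups. It stood from 6.57 to 7.93 on the other aged impaired arrays and from 7.41 to 8.01 in aged unimpaired animals. In young animals the values ran from 7.87 to 9.17, so the aged animals beside these 3 arrays also stood mostly below the young. Signal lost across the whole array stays open, since GCRMA removes differences shared by most probe sets of an array before this test. The lowest median deviation of 2718 probe sets of like brightness on these arrays was -0.02, so after normalization most of them did not share the low values. An allele carried by some animals, which could keep the probes from binding, stays open, since 1 probe set of Rnf6 passed the filter and 2 are needed to compare. Age and learning status both differ in the contrast that called Rnf6, aged impaired against young animals, and Rnf6 was not called between the aged groups. Both stay open as causes.

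Single arrays stood apart within their group, by a gap to the nearest animal divided by the range of the group above Dixon's 95% critical value for its size. Chance alone flags about 1 in 20 groups, which comes to 9.1 of the 181 groups examined among leading genes and markers, where 15 were found, and to 23 of 459 groups among list members, where 45 were found, 9 of them with aged impaired 2 standing apart. The lowest animals were aged unimpaired 8 for Cd74 (0.64), young 2 for Fcgr2b (0.59), young 7 for Rnf6 (0.73) and Pigt (0.53), young 9 for Ccer2 (0.50), aged impaired 3 and aged unimpaired 7 for Sema3c (0.53 and 0.63), young 8 for Slc6a6 (0.52), aged impaired 2 for Rerg (0.65) and Cmip (0.59), and young 4 for Gad1 (0.63). The highest were young 5 for C3 (0.59) and Sst (0.61), aged impaired 2 for Pigt (0.55) and young 1 for Cldn5 (0.50).

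Of 111 groups of list scores 8 stood out, against 5.6 by chance. The highest scores stood apart for reactive glia in young 6 (0.51), meninges in aged impaired 5 (0.68) and young 1 (0.57), CA3 markers in aged impaired 5 (0.55), dentate gyrus markers in aged unimpaired 6 (0.66), potassium channels in aged impaired 1 (0.61), endoplasmic reticulum stress in aged unimpaired 6 (0.70) and growth factors in young 1 (0.58). The meninges score was 0.82 in aged impaired 5 and 0.86 in young 1, the dentate gyrus score 0.41 in aged unimpaired 6.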

How the results depend on the processing

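The alternatives that left out aged impaired arrays 1 and 2 or used the gap as a covariate were chosen only after the result was seen. Of the values of named genes under the alternatives other than single arrays left out, 3018 kept their direction and their side of the threshold, 303 lost and 33 gained a call, and of those of gene lists 1718, 84 and 30. None of these changed direction past the threshold, with 0 reversed. For named genes the direction could not change under settings that leave the fitted difference as it is. These were no filter, the stricter filter, only the groups compared, and the prior with a trend and robust estimation. In the order aged impaired against young, aged unimpaired against young, aged impaired against aged unimpaired and both aged groups against young, limma called 1429, 302, 114 and 1010 probe sets, and without the filter, where more probe sets share the adjustment, 768, 126, 2 and 509, with 82 in the overlap of the comparisons with young. With the young animals divided, which leaves fewer per comparison, the overlap was 38 or 45. Between the aged groups quantile normalization gave 180 probe sets, array weights 222 (and 672 for aged unimpaired against young), and the fit to the groups compared 0 (2049 at an unadjusted p under 0.05), and for these the cause was not tested. With the replicate number as a block limma called 870, 86, 0 (1902 at an unadjusted p under 0.05) and 527 probe sets and 3 lists between the aged groups. The numbers do not pair the animals, since 3 of 23 arrays correlated best with their own number and 2 of 20 pairs exceeded a correlation of 0.1. Camera with an estimated correlation, which allows for genes of a list moving together, called 3, 1, 0 (1 at an unadjusted p under 0.05) and 2 lists. Without aged impaired arrays 1 and 2 there were 4 probe sets and 8 lists between the aged groups. With the gap as a covariate limma called 937 probe sets for aged impaired against young and 0 between the aged groups (1275 at an unadjusted p under 0.05). For both aged groups against young, the groups compared are all arrays, so that alternative gave no value. Leaving out 1 array at a time gave 1017 to 1808, 175 to 382, 2 to 447 and 615 to 1285 probe sets and 14 to 18, 13 to 17, 3 to 9 and 14 to 16 lists.

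Counts moved by more than 1.5 times for aged unimpaired against young without aged unimpaired 4 (175), aged unimpaired 6 (184) or young 3 (196), and for both aged groups without young 3 (615). Between the aged groups this held without aged impaired 1 (33), 2 (19), 3 (28), 5 (179), 6 (30), 7 (51) and 8 (25), aged unimpaired 1 (5), 4 (2), 6 (4), 7 (447) and 8 (13), and young 2 (75) and 8 (176), and for its lists without aged impaired 1 (9), 3 (8), 4 (3) or 8 (9) or aged unimpaired 2 (8). For these counts, and for those with the block, without aged impaired arrays 1 and 2 and with the gap, the cause was not tested. Signal over background limits what can be said of dim genes, since between 33.4% and 34.4% of probe sets lay at the floor on each array and differences there are compressed.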

Other observations

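Igf2, a growth factor made by the meninges and choroid plexus, had a wide spread between animals. It stood highest in aged impaired 5 (9.14) and young 1 (9.03), which also had high meninges scores, of which Igf2 is itself a member, and stood at -0.81 ± 0.34 SE in aged impaired and -1.29 ± 0.37 SE in aged unimpaired against young animals, without a call in either. With both aged groups averaged it was called lower than in young animals (-1.05 ± 0.30 SE, adjusted p = 0.0359).

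Across all arrays the first 3 principal components held 16.2%, 12.3% and 8.1% of the variance. The mean of the 99 probe sets called higher in aged impaired than in aged unimpaired animals was 7.64 in aged unimpaired 7, within the range of the aged impaired animals (7.56 to 8.01), and 6.64 to 7.31 in the other aged unimpaired animals. Young 1 (7.58) and young 5 (7.61) also lay within that range. These probe sets were chosen for the contrast of the aged groups, and the gap of aged unimpaired 7 (2.12) was the lowest of its group and within the aged impaired range (2.02 to 2.27). Aged unimpaired 7 stayed in its labelled group throughout.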
